A study of Mus musculus with 18 samples.

How the data were processed

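Tregs were sorted by flow cytometry from Foxp3-DTR/GFP reporter mice, and their RNA was measured by bulk RNA sequencing. There were 18 libraries: 6 of uninjured spleen and 3 each of injured bone, muscle, skin and heart. Every replicate of an injured tissue was pooled from 3 mice, while for spleen pooling is not stated. Per the labels, RNA was purified with a column kit for small samples and 1 ng of it was turned into libraries with the Ovation Solo kit. The deposited tables hold raw counts per gene, made before deposit by alignment to GRCm38 and read counting, where the submitters' processing notes name STAR, featureCounts and limma without versions. The annotation release, strand setting and treatment of multi-mapping reads or molecular identifiers are not given in the sources used here.

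The 2 tables, one for bone, muscle, skin and spleen and the other for heart and spleen, each held 46078 genes, and their spleen columns were identical. Of these genes 45143 (98%) had an entry in GENCODE release M21, which gave GRCm38 positions, while names and biotypes came from the deposited tables. Total counts ran from 5970346 to 15756884 in spleen, 11588253 to 22635760 in bone, 11582403 to 13358526 in muscle, 8375212 to 11907745 in skin and 11139361 to 12974890 in heart. Spleen libraries of the Endo naming style held at most 7230842 and those of the Tregs style at least 13873680. Between replicates of a group the spread of counts was 10.9 to 157 times that of counting alone (chi-square per degree of freedom, genes with at least 20 counts). Genes of ribosomal RNA and 7SK RNA took part in library sizes and tests, and no column was left out. For 2 bone libraries, called b and c, the column could be tied to the group but not to a replicate number.

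The comparisons, gene lists, rule for naming genes and most alternative analyses were fixed before the data were examined. Genes were filtered by filterByExpr with the groups, scaled by TMM and tested by the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment at FDR 0.05. The model held the group and the naming style of the library (Endo or Tregs), taken as a probable batch. It was fitted to the 15 libraries of the first table, to the 9 of the heart table and, for heart against the other tissues, to all 18. In the first table only spleen carried both styles, so that adjusted folds of bone and muscle rest on spleen replicates 4 to 6, those of skin on replicates 1 to 3, and any comparison of skin with bone or muscle also on the difference between spleen styles. Standard errors of log2 fold changes were derived from the F statistic. Levels are TMM-scaled CPM over all 18 libraries, as mean ± SD. Genes at 0 counts in a group were given a floor of 3 counts over the group. Such bounds cover counting error only and are not adjusted for naming style. The p-values measure the spread between libraries, each a pool of mice in the injured tissues.

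Genes named against spleen were the 8 highest and 8 lowest by log2 fold change among those past FDR 0.05 with a mean log2 CPM of at least 3 and no overlap between libraries of the 2 groups, and between tissues 5 and 5. Clone-named, immunoglobulin, T cell receptor and Y-linked genes and Xist were left out. To these came 10 fixed genes (among them Foxp3, Il2ra, Ctla4, Ikzf2, Areg, Il1rl1, Il10, Gata3 and Ccr7), up to 2 highest and 2 lowest of each list described, and the 10 highest and 10 lowest by mean among genes shared by all tissues. Of the list examples and further members, those whose call held under every alternative were preferred in the text. A few genes that these rules named are not reported here. Of 606 pairs of a gene and a comparison followed through the alternatives, 553 passed, 361 of those kept their call in every alternative, 192 lost it in at least 1, and 2 turned direction.

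Lists of genes, 28 in number, were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, which tests direction within a list only. Of 250 list tests 105 passed with the preset and 0 with an estimated correlation, so that each list call in the text depends on the preset. Lists with fewer than 3 measured genes were not tested. The lists covered Treg and T cell identity, tissue effector Tregs, naive T cells, repair factors, chemokine receptors, adhesion, coinhibitory receptors, helper lineages, cell cycle, immediate early genes, NF-kB, glycolysis and hypoxia, lipids and interferon. The other 13 held markers of macrophages, neutrophils, B cells, dendritic cells, CD8 T and NK cells, mast cells, erythroid cells, fibroblasts, endothelium, keratinocytes, skeletal muscle, heart muscle and bone.

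Alternatives fixed beforehand left out the naming style, used only spleen libraries of the same style, replaced it by replicate number as a block, and used RLE or upper-quartile scaling, DESeq2 1.42.0 or limma-voom (limma 3.58.1). Others dropped the filter, required CPM above 1 in 3 libraries, fitted only the 2 groups compared, required a change of at least 2-fold, left out each library in turn, or split the spleen libraries between tissues. Alternatives added after the data were seen used protein-coding genes only, left out the 2 spleen libraries richest in ribosomal RNA, or left out bone replicate c, which lay apart on the third principal component.

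The edgeR test was tried on simulated data with 200 changed genes. At 2-fold and 4-fold it found 58% and 89% of them for bone against spleen (3.92% of calls false), 49% and 93% for heart against spleen (2.74%), 52% and 88% for bone against muscle (7.89%), 48% and 88% for heart against muscle (7.48%), and 28% and 68% for muscle against skin (8.57%). The simulated changed genes were drawn from all but the least abundant ones, so the shares found among all tested genes may be lower. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.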

Results

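Gene expression was measured by bulk RNA sequencing in regulatory T cells (Tregs), the Foxp3-expressing CD4 T cells that restrain immune responses. The cells were sorted from male reporter mice aged 10 weeks, on day 7 after 1 of 4 injuries: a defect of the skull bone, a loss of quadriceps muscle, punch wounds of the skin, or a heart infarct made by tying the left coronary artery. Each injured tissue gave 3 libraries, every one pooled from 3 mice, and uninjured spleens gave 6 control libraries. The libraries carried names in 2 styles, here called Endo and Tregs. Spleen replicates 1 to 3, all of skin and heart replicate 1 had the Endo style, and all others the Tregs style. Folds below were adjusted for that style, while levels, in counts scaled to library size (CPM), are unadjusted means ± SD over all libraries of a group, so a fold can differ from the ratio of 2 levels.

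The first question, stated in the series title, was how Tregs of each injured tissue differed from spleen Tregs. No uninjured bone, muscle, skin or heart and no spleen of injured mice was measured. Effects of injury and of tissue therefore cannot be told apart, and rose or fell means higher or lower than in spleen. Transcripts of Foxp3, the lineage factor that defines Tregs, stood at 404 ± 40 CPM in spleen (n = 6), and at 751 ± 17 in bone, 710 ± 110 in muscle, 789 ± 63 in skin and 693 ± 63 in heart (n = 3 each). Foxp3 (ENSMUSG00000039521) was therefore higher in every injured tissue, with log2 fold changes of 0.87 ± 0.14, 0.79 ± 0.14, 0.94 ± 0.14 and 0.78 ± 0.14 (SE) and adjusted p of 9.6e-05, 0.00016, 1.6e-05 and 0.0012 in the same order. Ctla4, an inhibitory receptor, rose 2.2-fold in bone, 3.77-fold in muscle, 8.47-fold in skin and 5.18-fold in heart. Il2ra, a subunit of the interleukin-2 receptor, rose 1.7-fold, 1.83-fold, 2.77-fold and 2.36-fold in that order. Areg, a growth factor of the epidermal growth factor family, rose 7.04-fold, 18.8-fold, 60.8-fold and 23.1-fold, and Il10, an anti-inflammatory cytokine, 4.04-fold, 8.22-fold, 14.8-fold and 11.7-fold. Gata3, a transcription factor also used by type-2 helper cells, rose 2.02-fold, 2.42-fold, 3.05-fold and 2.78-fold. Bone and muscle folds rest on the Tregs-style spleen libraries and skin folds on the Endo-style ones. The order of folds therefore need not follow that of levels. Il10 stood at 2.6 to 8.72 CPM in Endo and 12.8 to 20.8 CPM in Tregs spleen libraries. It reached 91.1 to 193 CPM in muscle and 57.1 to 109 CPM in skin. Areg stood at 3.81 to 11.7 and 14.6 to 32.6 CPM in those spleen libraries. It reached 263 to 648 CPM in muscle and 444 to 647 CPM in skin. Ikzf2, the transcription factor Helios, stood at 1140 ± 160 CPM in spleen and passed the test in bone (1.38-fold), muscle (1.37-fold) and skin (1.81-fold) but not in heart (1440 ± 130 CPM, adjusted p = 0.17). The bone call on Ikzf2 was lost without any 1 bone library or without spleen replicate 4 or 5 (adjusted p up to 0.11), and the muscle call without muscle replicate 2 or spleen replicate 4 (up to 0.091). Ccr7, a homing receptor, passed only in skin (log2 fold change -1.92 ± 0.45, adjusted p = 0.0076), a call that was lost without the 2 spleen libraries richest in ribosomal RNA (adjusted p = 0.36). Its adjusted p was 0.2 in bone, 0.071 in muscle and 0.74 in heart. Whether Ikzf2 or Ccr7 differed between tissues is a separate test, and none of the direct comparisons passed for either gene.

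**Figure D1:**
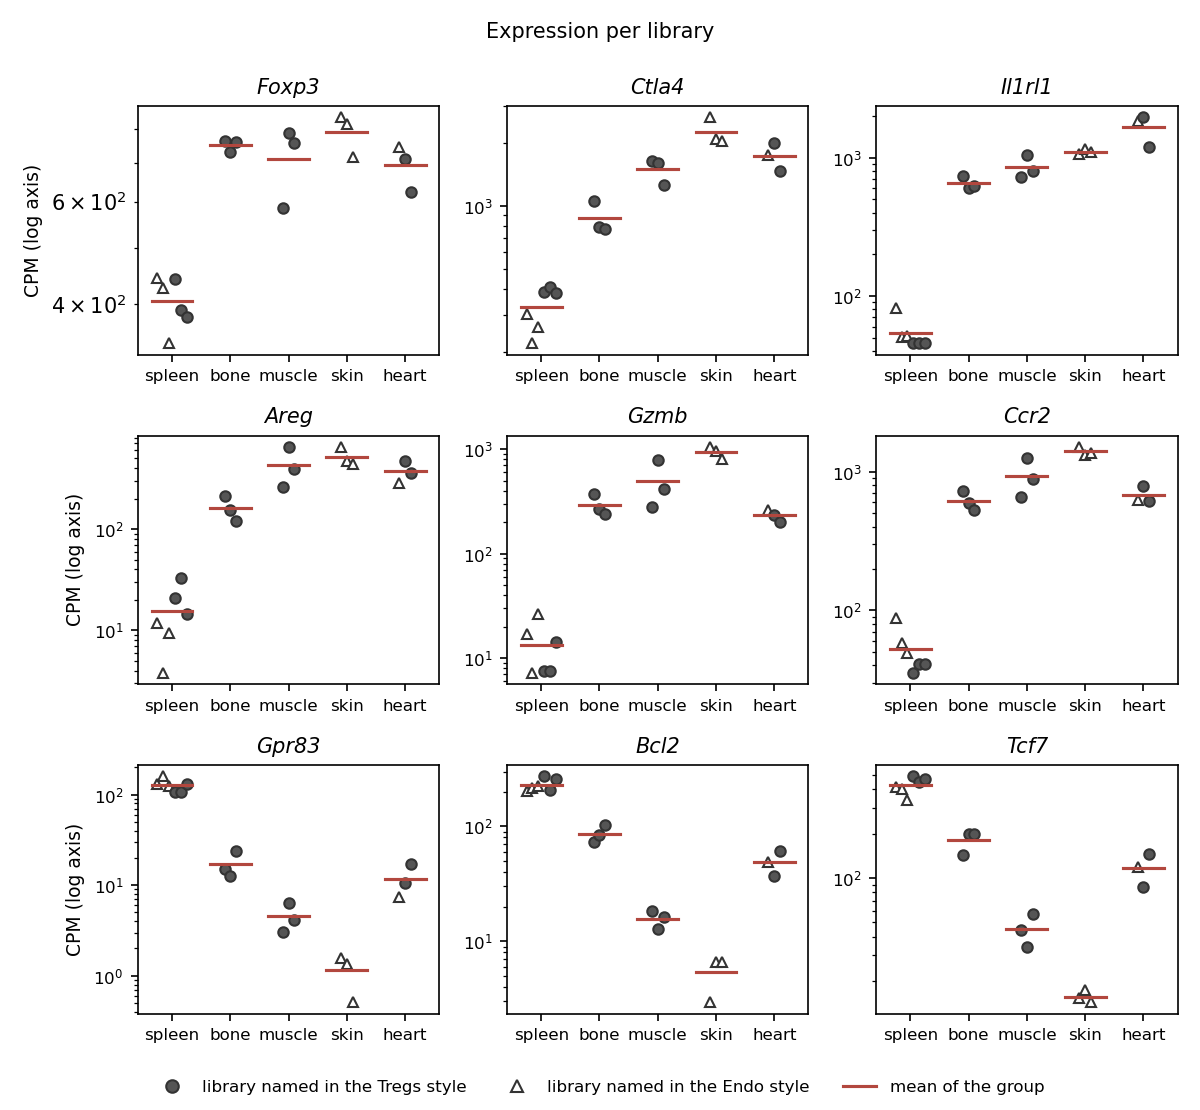
Levels of 9 genes in each of the 18 libraries, in CPM on a log axis, for spleen (n = 6) and the 4 injured tissues (n = 3 each); circles are libraries named in the Tregs style, triangles those named in the Endo style, and the red line is the mean of the group. All libraries of injured tissues lie above the spleen libraries for Foxp3, Ctla4, Il1rl1, Areg, Gzmb and Ccr2, and below them for Gpr83, Bcl2 and Tcf7.

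In Tregs of injured bone, Lmna (ENSMUSG00000028063, chromosome 3, 88480147 to 88509956, GRCm38), which encodes the nuclear lamins A and C, rose from 10.5 ± 3.4 to 384 ± 110 CPM (log2 fold change 5.29 ± 0.37, adjusted p = 4.4e-07). Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), the protease granzyme B, rose from 13.4 ± 7.7 to 293 ± 70 CPM (4.89 ± 0.53, adjusted p = 6.5e-05). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415), the receptor for interleukin-33, rose 14.1-fold from 53.6 ± 14 to 653 ± 72 CPM (adjusted p = 9.3e-12). The chemokine receptor genes Ccr2 and Cxcr6 rose 15.6-fold and 17.8-fold, and Slc15a3, a lysosomal peptide transporter, 15.6-fold. Myadm, a membrane protein gene, rose 13.7-fold, and Ctla2a, a protease inhibitor gene whose reads can be shared with its close copy Ctla2b, 13.6-fold. Among the lowest genes were Igfbp4, which binds insulin-like growth factors (12.2-fold lower, 3.85 ± 0.73 against 59.3 ± 21 CPM), and Rmrp, the RNA of a mitochondrial RNA processing ribonuclease (13.5-fold lower, 292 ± 38 against 2800 ± 1700 CPM). The other 6 among the lowest 8 were small nucleolar RNA genes, which guide the modification of ribosomal RNA: Snord49b, Snora57, Snora78, Snord8, Snord15a and Snord17, with log2 fold changes from -6.55 ± 0.91 to -3.27 ± 0.57. Spleen replicate 4 was the highest library for each of them, with Snord49b at 1120 CPM against 349 and 163 in replicates 5 and 6. In Endo-style spleen libraries Snord49b stood at only 8.31 to 32.8 CPM, and in bone at 4.3 to 7.64 CPM.

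Against spleen, 2312 of 15617 genes changed in bone, 1325 higher and 987 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 3 and 6). Of the 20 tissue effector Treg genes, 19 rose and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 4.2e-18, and adjusted p = 0.06 with an estimated correlation). NF-kB targets and TNF receptor family genes, such as the costimulatory receptor gene Tnfrsf9 (4.25-fold) and the NF-kB regulator Bcl3 (2.6-fold), rose in 12 of 15 cases, also 12 adjusted over the list alone (adjusted p = 2.9e-10, and adjusted p = 0.054 with an estimated correlation). Glycolysis and hypoxia genes, such as the oxygen sensor Egln3 (8.45-fold) and the mitophagy gene Bnip3 (3.83-fold), rose in 11 of 16 cases, 12 adjusted over the list alone (adjusted p = 9.7e-09, and adjusted p = 0.054 with an estimated correlation). Among 16 naive and lymphoid-resident T cell genes 12 fell, such as the adhesion-linked actinin gene Actn1 (4.18-fold) and the survival gene Bcl2 (2.91-fold), 1 rose and 3 did not pass (adjusted p = 3.9e-09, and adjusted p = 0.11 with an estimated correlation). Adjusted over the list alone, 13 of them fell and 1 rose, the latter being Il7r, the interleukin-7 receptor (2.67-fold). Of 18 cell cycle genes 6 rose, such as the cyclin gene Ccna2 (2.34-fold), and 12 did not pass, while 11 rose adjusted over the list alone (adjusted p = 0.00031, and adjusted p = 0.46 with an estimated correlation). Beside these groups, markers of B cells were lower in 2 of 10 cases and markers of erythroid cells in 4 of 6. Of the 16 highest and lowest genes, 14 kept their call under every alternative. Snora78 and Snord15a lost it against the 3 spleen libraries of the same naming style alone (adjusted p = 0.055 and 0.068).

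In Tregs of injured muscle, Gzmb rose 49.8-fold to 492 ± 260 CPM (log2 fold change 5.64 ± 0.54, adjusted p = 1.6e-05) and Lmna 49-fold to 482 ± 94 CPM (5.62 ± 0.38, adjusted p = 1.1e-07). Cxcr6 rose 34.2-fold, Ctla2a 26-fold, Ky, which encodes a peptidase-like protein of muscle sarcomeres, 24.9-fold, Slc15a3 24.8-fold, Ccr2 23.6-fold and the metalloprotease gene Adam8 23.3-fold. In the other direction Igfbp4 was 36.1-fold lower, and Treml2, an immunoglobulin-family receptor gene, 27.3-fold lower. Gpr83 (ENSMUSG00000031932, chromosome 9, 14860210 to 14870789), a G protein-coupled receptor gene enriched in Tregs, fell from 126 ± 20 to 4.52 ± 1.7 CPM (-4.67 ± 0.28, adjusted p = 1.4e-10). Dtx1, a ubiquitin ligase gene of the Notch pathway, fell 23.4-fold, the neuronal vesicle gene Nsg2 21.8-fold, the ganglioside synthase gene St8sia1 21.8-fold, the small nucleolar RNA gene Snord8 29.8-fold and Rmrp 19.5-fold.

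Muscle held 3984 changed genes of 15617 against spleen, 2222 higher and 1762 lower (n = 3 and 6). All 20 tissue effector genes rose, and all 20 adjusted over the list alone (adjusted p = 5.1e-19, and adjusted p = 0.054 with an estimated correlation), as did all 15 NF-kB and TNF receptor genes on both counts (adjusted p = 3.5e-13, and adjusted p = 0.054 with an estimated correlation). The latter included Tnfrsf9 (5.87-fold) and the adhesion gene Icam1 (3.94-fold). Glycolysis and hypoxia genes, such as Egln3 (10.5-fold) and the triosephosphate isomerase gene Tpi1 (3.94-fold), rose in 12 of 16 cases, also 12 adjusted over the list alone (adjusted p = 7e-08, and adjusted p = 0.054 with an estimated correlation). Cell cycle genes, such as the cyclins Ccnb1 (3.82-fold) and Ccna2 (3.77-fold), rose in 14 of 18 cases, 16 adjusted over the list alone (adjusted p = 9.5e-08, and adjusted p = 0.28 with an estimated correlation). Muscle replicate 1 stood above replicates 2 and 3 in some of them, with Ccnb1 at 33.6 against 11.8 and 14.2 CPM and Ube2c at 70.1 against 21 and 31.4 CPM. Naive genes fell in 14 of 16 cases, 15 adjusted over the list alone, with Bcl2 15.8-fold and the repressor gene Bach2 11.4-fold lower (adjusted p = 3.6e-13, and adjusted p = 0.054 with an estimated correlation). Dapl1 had no count in any muscle library, at least 89.7-fold below spleen, and Il7r again rose (1.75-fold). Beside these groups all 10 markers of B cells fell in muscle, and 5 of 6 erythroid markers. All 16 of the highest and lowest genes kept their call under every alternative.

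Skin Tregs held the highest levels of several immune receptors and effectors. Havcr2, the inhibitory receptor TIM-3, rose from 2.84 ± 1.1 to 153 ± 26 CPM (log2 fold change 6.01 ± 0.34, adjusted p = 3.7e-11). Areg (ENSMUSG00000029378) rose from 15.5 ± 10 to 521 ± 110 CPM (5.93 ± 0.52, adjusted p = 4e-06) and Gzmb to 938 ± 130 CPM (5.74 ± 0.55, adjusted p = 1e-05). Lmna rose 47.9-fold, the small GTPase gene Gem 36.6-fold, the Notch ligand gene Jag1 35.2-fold and the cytoskeletal linker gene Gas2l3 31.9-fold. Bcl2 (ENSMUSG00000057329, chromosome 1, 106538178 to 106714274) fell from 230 ± 29 to 5.37 ± 2.1 CPM (-5.36 ± 0.24, adjusted p = 3.5e-13). P2rx7, an ATP-gated ion channel gene, was 46.9-fold lower, Treml2 49.5-fold and St8sia1 38.8-fold. Igfbp4 stood at 0.446 ± 0.5 CPM and Gpr83 at 1.14 ± 0.56 CPM. Art2b, an ADP-ribosyltransferase gene, fell 73.5-fold and Tgtp1, an interferon-induced GTPase gene, 39.9-fold, but both can share reads with near-identical copies and their values are uncertain.

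Between skin and spleen 4342 of 15617 genes changed, 2347 higher and 1995 lower (n = 3 and 6). The 20 tissue effector genes (adjusted p = 3e-21, and adjusted p = 0.054 with an estimated correlation), the 15 NF-kB and TNF receptor genes (adjusted p = 3.7e-14, and adjusted p = 0.054 with an estimated correlation) and the 18 cell cycle genes (adjusted p = 2.5e-12, and adjusted p = 0.17 with an estimated correlation) all rose, and all of them also adjusted over the list alone. Examples were Tnfrsf9 (10.2-fold), the costimulatory receptor gene Tnfrsf4 (6.16-fold) and Ccna2 (9.45-fold). Glycolysis and hypoxia genes rose in 14 of 16 cases, as many adjusted over the list alone, with Egln3 16.3-fold and Tpi1 5.6-fold higher (adjusted p = 2.5e-10, and adjusted p = 0.054 with an estimated correlation). Of the naive genes 15 of 16 fell and Il7r rose 3.96-fold, with the same counts adjusted over the list alone (adjusted p = 6.1e-11, and adjusted p = 0.072 with an estimated correlation). Interferon response genes fell in 9 of 15 cases and rose in none, such as Usp18, which curbs interferon signalling (7.26-fold lower), with the same counts adjusted over the list alone (adjusted p = 0.0092, and adjusted p = 0.46 with an estimated correlation). Markers of B cells were lower in 8 of 10 cases beside them. The count of changed genes fell to 2548 without the 2 spleen libraries richest in ribosomal RNA, replicates 1 and 2, which leaves a single spleen library of the skin naming style. All 16 of the highest and lowest genes kept their call under every alternative.

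In Tregs of the infarcted heart, Il1rl1 reached the highest mean of any group, 1660 ± 420 CPM (log2 fold change 5.02 ± 0.20, adjusted p = 2.3e-09). Dgat1 and Dgat2, whose enzymes make triglycerides, rose 23.6-fold (to 448 ± 230 CPM) and 36.4-fold (to 109 ± 22 CPM). Pparg, a lipid-sensing transcription factor of fat tissue Tregs, rose 29-fold. Ctla2a rose 66.1-fold, Cxcr6 44.2-fold, Ky 43.4-fold, Areg 23.1-fold and Slc15a3 20.7-fold. Transcripts of Il5, a cytokine that acts on eosinophils, were at 15.4 ± 2.4 CPM in heart and at 0 counts in spleen, at least 331-fold higher (floor of 3 counts over the spleen libraries). The lowest genes were Dtx1 (16.1-fold), Gpr83 (10.9-fold), the actin-binding gene Synpo (9.38-fold), Treml2 (9.03-fold), Arhgap20 (8.85-fold), the guanylate cyclase gene Gucy1a3 (8.61-fold), Nsg2 (8.47-fold) and Tgfbr3, a co-receptor of transforming growth factor beta (8.22-fold).

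The heart comparison gave 3043 changed genes of 15025, 1772 higher and 1271 lower (n = 3 and 6). All 20 tissue effector genes (adjusted p = 1.3e-18, and adjusted p = 0.054 with an estimated correlation) and all 15 NF-kB and TNF receptor genes (adjusted p = 1.5e-10, and adjusted p = 0.12 with an estimated correlation) rose, as many as adjusted over the list alone. Cell cycle genes, such as Ccnb1 (3.46-fold), rose in 12 of 18 cases, 15 adjusted over the list alone (adjusted p = 2.1e-06, and adjusted p = 0.39 with an estimated correlation). Heart replicate 3 stood above replicates 1 and 2 in such genes, with Ccnb1 at 31 against 8.65 and 12.3 CPM, and Plk1 at 23.9 against 4.8 and 7.86 CPM, where spleen libraries reached 11.8 CPM. Glycolysis and hypoxia genes, such as Egln3 (16.4-fold) and Tpi1 (3.26-fold), rose in 10 of 16 cases, 11 adjusted over the list alone (adjusted p = 2.6e-06, and adjusted p = 0.054 with an estimated correlation). Of the naive genes 14 of 16 fell on both counts, with Id3, an inhibitor of E proteins, 7.34-fold and Igfbp4 6.68-fold lower, and Il7r rose 2.54-fold (adjusted p = 8.9e-09, and adjusted p = 0.18 with an estimated correlation). Markers of B cells were lower in 3 of 10 cases and erythroid markers in 3 of 6. Of the 16 highest and lowest genes 15 kept their call under every alternative, and Tgfbr3 lost it with the replicate number as a block (adjusted p = 0.053).

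**Figure D2:**
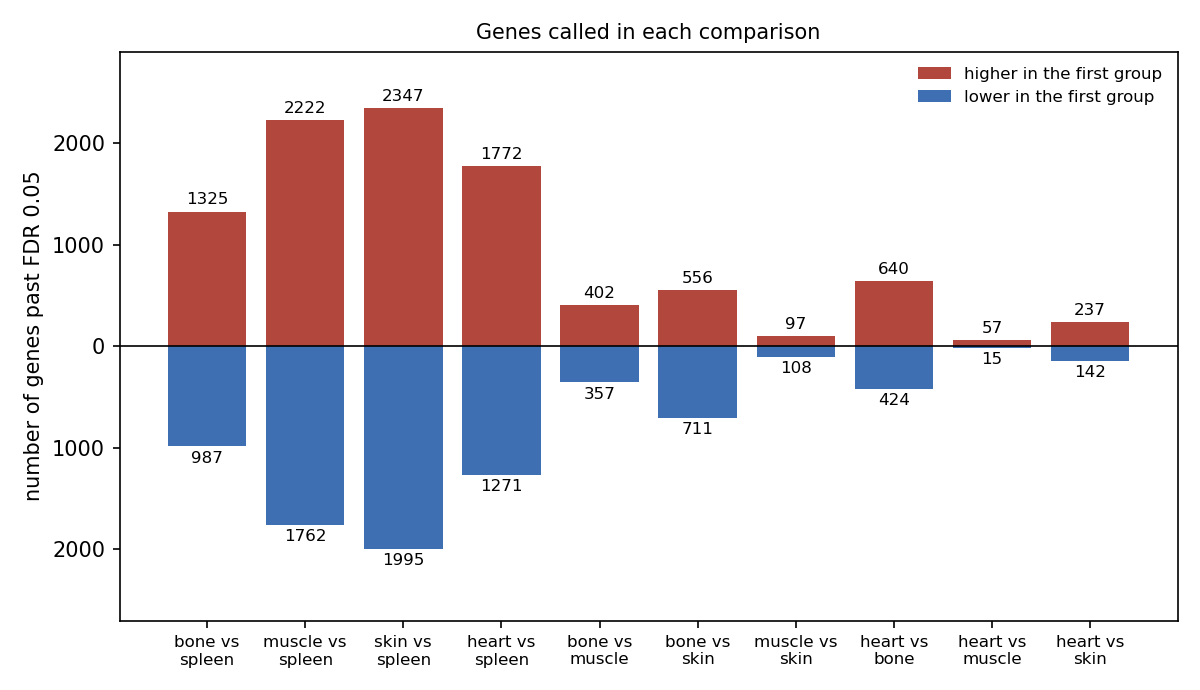
Number of genes past FDR 0.05 in each of the 10 comparisons, with genes higher in the first-named group drawn upward (red) and genes lower drawn downward (blue). The 4 comparisons with spleen hold 2312 to 4342 genes, and those between injured tissues 72 to 1267.

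Several other gene groups were compared with spleen in all 4 tissues, and their counts are given in the order bone, muscle, skin and heart. Of 15 Treg identity genes 9, 10, 9 and 8 rose and 2, 2, 4 and 2 fell, the latter always including Gpr83 and the folate receptor family gene Izumo1r. Adjusted over the list alone 9, 11, 10 and 8 rose and 2, 3, 4 and 2 fell. The camera adjusted p was 0.0028, 0.0031, 0.0053 and 0.0058, and each call was lost, with adjusted p = 0.36, 0.36, 0.39 and 0.33 with an estimated correlation. Itgae, an integrin gene used to bind epithelium, rose 3.6-fold, 4.48-fold, 10.1-fold and 4.57-fold. Of 14 chemokine receptor genes 9, 11, 10 and 11 rose and 1, 1, 3 and 1 fell, against 10, 11, 11 and 11 risen and 1, 2, 3 and 1 fallen adjusted over the list alone. Adjusted p was 7.8e-09, 1.6e-06, 2.5e-05 and 7e-08, and adjusted p = 0.054, 0.054, 0.077 and 0.077 with an estimated correlation. Ccr1, a receptor for inflammatory chemokines, went from 1.3 CPM in spleen to 64.3, 97.5, 104 and 128 CPM, while Cxcr5, a receptor for B cell follicles, fell 3.12-fold, 11.8-fold, 31.4-fold and 3.59-fold. The bone call on Cxcr5 was lost without bone replicate 1 or b or spleen replicate 5 or 6 (adjusted p up to 0.088). Of 15 adhesion and integrin genes 8 rose in each tissue and 1, 1, 3 and 2 fell, with 9, 8, 9 and 8 risen and 2, 3, 3 and 2 fallen adjusted over the list alone. Adjusted p was 0.0016, 0.0021, 0.011 and 0.0091, and adjusted p = 0.17, 0.18, 0.23 and 0.19 with an estimated correlation. Itga4, an integrin gene used in homing, fell 6.52-fold in skin.

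Of 12 coinhibitory receptor and ectoenzyme genes 6, 7, 6 and 7 rose and 1, 2, 3 and 2 fell in the same tissue order, with 6, 7, 6 and 8 risen and 1, 3, 4 and 3 fallen adjusted over the list alone. Adjusted p was 0.025, 0.018, 0.029 and 0.018, and adjusted p = 0.31, 0.28, 0.32 and 0.34 with an estimated correlation, and the skin call was lost with the replicate block (0.059). Havcr2 rose 17.5-fold, 22.5-fold, 64.5-fold and 20.4-fold, whereas the inhibitory receptor gene Btla fell 1.65-fold, 2-fold, 1.92-fold and 1.77-fold. Of 17 repair factor genes 5, 7, 6 and 8 rose and 1, 2, 2 and 2 fell, with 6, 8, 6 and 11 risen and 1, 2, 2 and 3 fallen adjusted over the list alone. Adjusted p was 0.02, 0.012, 0.025 and 0.0016, and adjusted p = 0.19, 0.17, 0.2 and 0.13 with an estimated correlation. Fgf2, a fibroblast growth factor gene, fell 4.16-fold, 6.52-fold, 28.3-fold and 12.9-fold, the bone call being lost without bone replicate 1 or c or spleen replicate 5 or 6 (adjusted p up to 0.11), and Csf1, the macrophage growth factor gene, fell 2.79-fold in skin and 3.05-fold in heart. Of the measured helper T cell genes (12, and 11 in heart) 4, 6, 6 and 6 rose and 1, 2, 1 and 0 fell, with 5, 6, 6 and 6 risen and 3, 3, 1 and 0 fallen adjusted over the list alone. Adjusted p was 0.3 in bone, where the list did not pass, and 0.027, 0.017 and 1e-05 in the others, with adjusted p = 0.21, 0.19 and 0.054 with an estimated correlation. Transcripts of the interleukin-17 gene Il17a were at 0 counts in spleen. Without adjustment for style they were at least 52.1-fold, 46.4-fold, 278-fold and 57.3-fold higher in the tissues, with the floor set over all spleen libraries. Over the shallower Endo spleen libraries alone, which match skin in style, the bound for skin would be lower. Of the lipid and sterol genes (15 measured, 14 in heart) 3, 6, 5 and 5 rose and 1, 3, 4 and 2 fell, with 6, 6, 5 and 5 risen and 1, 3, 4 and 3 fallen adjusted over the list alone, and the list did not pass (adjusted p of 0.095, 0.2, 0.6 and 0.16).

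Immediate early genes, which sorting and tissue digestion also raise, rose in 6, 7, 8 and 8 of 18 cases and fell in 1, 2, 3 and 0, with 6, 8, 8 and 9 risen and 2, 2, 3 and 1 fallen adjusted over the list alone. They passed camera in skin (adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation) and heart (adjusted p = 0.0017, and adjusted p = 0.37 with an estimated correlation), with adjusted p of 0.097 in bone and 0.11 in muscle, the latter 0.0065 with the replicate block. The block sets muscle against Endo-style spleen libraries without adjustment for style. By camera the list was itself lower in that style (adjusted p = 0.00034, and 0.61 with an estimated correlation). Egr2, an early response factor gene downstream of the T cell receptor, fell 2.24-fold in bone, 3.93-fold in muscle and 6.11-fold in skin, and its bone call was lost without bone replicate c or spleen replicate 5 (adjusted p of 0.059 and 0.12). Of 15 interferon response genes 0 rose and 3 fell in bone, 2 rose and 2 fell in muscle, and 1 rose and 3 fell in heart, the same as adjusted over the list alone except for 3 risen in muscle. This list did not pass in those tissues (adjusted p of 0.061, 0.88 and 0.92). Gbp2, an interferon-induced GTPase gene, fell 1.89-fold in bone and 1.65-fold in muscle. Of 12 T cell identity genes 0, 4, 2 and 2 rose and 1, 0, 2 and 0 fell, and the list did not pass (adjusted p of 0.45, 0.55, 0.76 and 0.38). Adjusted over the list alone the counts were equal except for 0 fallen in bone. Cd28, a costimulatory receptor gene, rose 1.49-fold in muscle and 1.5-fold in skin.

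Markers of other cell types that could reach the sort were measured as well. All 10 B cell markers fell in muscle (adjusted p = 5.6e-08, and adjusted p = 0.054 with an estimated correlation), 8 in skin (adjusted p = 0.0013, and adjusted p = 0.19 with an estimated correlation), 3 in heart (adjusted p = 0.014, and adjusted p = 0.55 with an estimated correlation) and 2 in bone (adjusted p = 0.085), with 10, 8, 4 and 2 adjusted over the list alone. Ms4a1, the B cell antigen CD20, had no count in muscle against 15.2 ± 5.6 CPM in spleen, at least 189-fold lower. Erythroid markers fell in 4, 5, 3 and 3 of 6 cases in the order bone, muscle, skin and heart, with 4, 5, 3 and 4 adjusted over the list alone. Adjusted p was 3.6e-07, 1e-05, 0.0093 and 0.0031, and adjusted p = 0.054, 0.054, 0.19 and 0.23 with an estimated correlation. With the replicate block the heart calls on markers of B cells (adjusted p = 0.095), erythroid cells (0.46) and fibroblasts (0.11) were lost. Hbb-bt, a beta globin gene whose reads can be shared with Hbb-bs, was at 0 counts in bone, muscle and skin. Without adjustment for style it was at least 111-fold, 66.5-fold and 49.2-fold lower than in spleen. Its spleen counts were 26 in the Endo and 422 in the Tregs libraries. The bound for skin is therefore lower against spleen libraries of its own style, Endo. Fibroblast markers (8 measured, 5 in heart) rose in 2, 2, 0 and 1 cases, with 5, 5, 0 and 1 adjusted over the list alone. The list passed in bone (adjusted p = 0.0043, and adjusted p = 0.41 with an estimated correlation) and heart (adjusted p = 0.026, and adjusted p = 0.46 with an estimated correlation), with adjusted p of 0.095 in muscle and 0.15 in skin. Fn1, the matrix gene fibronectin, stood at 1.26 ± 1.6 CPM in spleen, 19.9 ± 11 in bone and 11.3 ± 2.1 in muscle. Macrophage and monocyte markers rose in 1, 2, 2 and 1 of 12 cases and fell in 3, 5, 2 and 0, with equal counts adjusted over the list alone, and did not pass (adjusted p of 0.12, 0.17, 0.53 and 0.93). Dendritic cell and MHC class II markers rose in 0, 1, 3 and 1 of the measured cases (10, and 8 in heart), as many adjusted over the list alone. They passed in skin (adjusted p = 0.011, and adjusted p = 0.47 with an estimated correlation) and not elsewhere (adjusted p of 0.66, 0.6 and 0.9). Neutrophil markers (6 measured) rose in 1, 1, 2 and 1 cases and fell in 0, 2, 2 and 0, with 4 fallen in skin adjusted over the list alone, and the list did not pass (adjusted p of 0.87, 0.75, 0.43 and 0.42).

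The remaining markers were few. No marker of CD8 T and NK cells passed edgeR's test in any tissue (9 measured, 7 in heart), and the list had adjusted p of 1, 0.89, 0.89 and 0.15. Endothelial markers fell in 0, 1, 1 and 1 cases of the 4 measured (3 in heart), the gene being Pecam1, which T cells also carry, and did not pass as a list (adjusted p of 0.5, 0.79, 0.26 and 0.21). Pecam1 fell 2.4-fold in skin and 1.67-fold in heart. Keratinocyte markers (3 measured) rose in 1 case in muscle, and skeletal muscle markers (4 measured, 3 in heart) in 1 case, also in muscle. Neither list passed in any tissue, with adjusted p of 0.89 for keratinocyte markers in skin and 0.54 for skeletal muscle markers in muscle. Of 7 mast cell markers only Kit was measured, and it rose 9.81-fold, 8.46-fold, 12.8-fold and 8.08-fold. For markers of cardiomyocytes and of osteoblasts 2 genes each were measured, too few for a list test. Ryr2, a calcium channel gene of the heart, was at 8.69 ± 4.5 CPM in spleen and 0.664 ± 0.82 in heart, and Runx2, a transcription factor of bone and T cells, rose 2.73-fold in bone, 4.14-fold in muscle, 3.88-fold in skin and 3.02-fold in heart.

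**Figure D3:**
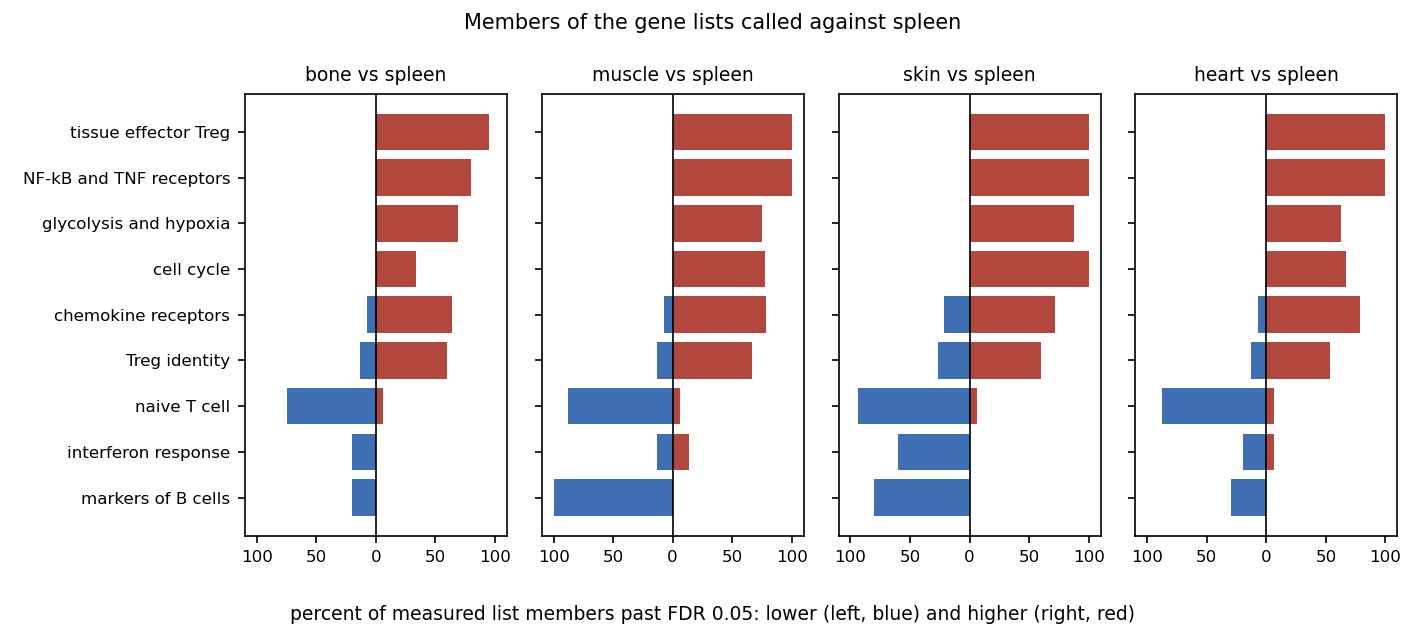
Percent of the measured members of 9 gene lists past FDR 0.05 against spleen in each injured tissue, lower to the left (blue) and higher to the right (red). All members of the tissue effector list rose in muscle, skin and heart, and all 10 B cell markers fell in muscle.

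RNA classes also differed between groups. Genes of ribosomal RNA and 7SK RNA took 19.2% of counts on average in spleen (13.5 to 27.8% over 6 libraries), 7.65% in bone (6.76 to 8.55%), 10% in muscle (8.93 to 11.4%), 16% in skin (12 to 19%) and 11.6% in heart (11.2 to 12%). Of 304 small RNA genes tested, 117 were lower and 1 higher in bone, 118 lower and 3 higher in muscle and 40 lower and 1 higher in skin, while in heart 6 of 297 were lower and 3 higher. The heart libraries differed among themselves, with Rmrp at 4060 CPM in replicate 1 against 584 and 496 in replicates 2 and 3, and Rpph1 at 3750 against 758 and 718. The median log2 fold changes of the small RNA genes were -1.85 in bone, -1.91 in muscle, -0.81 in skin and -0.49 in heart. Many of these genes lie in introns of other genes, and the strand handling of the counts is unknown, so their reads cannot all be assigned with certainty. Spleen replicates 1 and 2 had the highest ribosomal shares, 27.8% and 23.7%.

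A further question was which changes the injured tissues shared. The same direction past FDR 0.05 in all 4 was seen for 1083 of 14849 genes, 788 higher and 295 lower, against 3.28 and 1.33 for independent lists of those sizes. In simulated unchanged groups with a common set of simulated spleen libraries, 0 genes changed the same way in all, by edgeR at the same threshold. No gene did so in any pair of tissues either, so the simulation cannot tell how far shared controls raise the overlap of changed genes. Simulated log2 fold changes correlated at r = 0 (bone and skin) to 0.5 (bone and muscle), against 0.53 and 0.74 in the data. For bone, muscle and skin alone 1351 of 15617 genes changed the same way, 923 higher and 428 lower (28.3 and 14.2 for independent lists). With the spleen libraries split between the tissues, the number was 894 (662 higher and 232 lower, against 10.3 and 4.43). The style term was still estimated from all spleen libraries together, so this count is not free of shared controls. Genes higher in all 4 tissues included Ccr1 (mean log2 fold change 6.61), the leukotriene receptor gene Ltb4r1 (5.96), Frmd5 (5.68), the matrix gene Npnt (5.63), the metallothionein gene Mt1 (5.40), the methionine sulfoxide reductase gene Msrb3 (5.21), Lmna (5.15), Gzmb (5.13) and the annexin gene Anxa1 (4.92). Pcsk1, a prohormone-cutting protease, was at 0.429 CPM in spleen and 87.2, 93.5, 115 and 131 CPM in bone, muscle, skin and heart. Genes lower in all 4 included Gpr83 (-4.44), Dtx1 (-3.96), Treml2 (-3.94), St8sia1 (-3.60), Art2b (-3.53), Nsg2 (-3.43), Bcl2 (-3.29), Cxcr5 (-3.00), Actn1 (-3.00) and Bach2 (-2.98). In skin the calls on Pcsk1 and Ltb4r1 were lost by limma-voom (adjusted p = 0.06 and 0.11).

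Injured tissues were next compared with each other, starting with bone and muscle, whose libraries carried the same naming style. Bcl2 was 5.44-fold higher in bone (86.1 ± 14 against 15.8 ± 2.9 CPM, log2 fold change 2.44 ± 0.20, adjusted p = 3.4e-07, n = 3 each). Tcf7, a transcription factor of naive and memory T cells, was 3.99-fold higher (180 ± 31 against 45 ± 12 CPM, adjusted p = 3.4e-07). Art2b was 7.34-fold, the bacterial sensor gene Nod1 5.28-fold, the tyrosine kinase gene Syk 4.74-fold and the nuclear protein gene Aff3 4.39-fold higher. Lower in bone were the granule protein gene Nkg7 (3.43-fold), the chemokine gene Cxcl10 (3.16-fold), the type-1 helper factor gene Tbx21 (2.96-fold), the kinetochore gene Spc25 (2.92-fold) and the replication licensing gene Cdc6 (2.89-fold). Ctla4 was 1.72-fold lower in bone (adjusted p = 0.0055), and Foxp3, Il2ra and Ikzf2 did not pass (adjusted p of 0.81, 0.77 and 0.98).

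Between bone and muscle 759 genes changed, 402 higher and 357 lower in bone, of 15617 tested. Of 16 naive genes 10 were higher in bone and none lower, 15 adjusted over the list alone (adjusted p = 9.1e-14, and adjusted p = 0.054 with an estimated correlation). B cell markers were higher in 7 of 10 cases beside them, 10 adjusted over the list alone (adjusted p = 1.9e-11, and adjusted p = 0.054 with an estimated correlation), and Ms4a1, at 0 counts in muscle, was at least 68.5-fold higher. Tissue effector genes were lower in bone in 7 of 20 cases, 14 adjusted over the list alone, such as the transcription factor gene Nfil3 (2.01-fold) and the chemokine receptor gene Ccr8 (2.22-fold) (adjusted p = 8.9e-09, and adjusted p = 0.19 with an estimated correlation). NF-kB genes were lower in 7 of 15 cases, 14 adjusted over the list alone, such as Rel (1.69-fold) and Cd83 (1.73-fold) (adjusted p = 4.1e-08, and adjusted p = 0.072 with an estimated correlation). Cell cycle genes were lower in 3 of 18 cases, 4 adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.39 with an estimated correlation). The 3 were the replication genes Mcm2 (45.5 to 62.7 CPM in bone and 78.9 to 86.3 in muscle), Mcm3 (59.5 to 92.4 and 116 to 127) and Mcm5 (41.1 to 51.5 and 79.6 to 95.3). In mitotic genes the difference lay mainly in muscle replicate 1, with Ccnb1 at 9.08 to 12.4 CPM in bone and 33.6, 11.8 and 14.2 in muscle, and Ube2c at 26 to 44.6 and 70.1, 21 and 31.4. Lists of helper (adjusted p = 0.032), T cell identity (0.023) and interferon genes (0.0072) also passed as lower in bone, with adjusted p = 0.23, 0.37 and 0.45 with an estimated correlation. The call on Nfil3 needed the style covariate (adjusted p = 0.22 without it), and that on Ctla4 was lost without bone replicate c (0.054). Of the 10 highest and lowest genes 7 kept their call under every alternative. Syk lost it without bone replicate b or c or muscle replicate 2 or 3 (adjusted p up to 0.07), Tbx21 without bone b or c or muscle 1 (up to 0.063) and Spc25 without any 1 bone library or muscle 1 (up to 0.23). Without 1 library the count was 323 (bone b), 256 (bone c), 464 (muscle 1) or 431 (muscle 2).

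Bone and skin differed in 1267 genes, 556 higher and 711 lower in bone. Naive genes were again higher in bone: Bcl2 14.1-fold (86.1 ± 14 against 5.37 ± 2.1 CPM, log2 fold change 3.82 ± 0.30, adjusted p = 5.1e-08), Bach2 9.9-fold and Tcf7 9.38-fold (180 ± 31 against 15.7 ± 1.5 CPM, adjusted p = 2.3e-08). P2rx7 was 24.2-fold and the zinc finger gene Zfp827 12.8-fold higher, and the integrin gene Itga4 6.16-fold (1010 ± 92 against 120 ± 16 CPM). Lower in bone were Nfil3 (13-fold, 61.3 ± 13 against 291 ± 15 CPM, adjusted p = 1.1e-08), the vesicle gene Mreg (9.22-fold), Areg (8.63-fold), Hist1h4a (7.96-fold) and Hist1h4j (6.87-fold), the last 2 being histone genes whose reads near-identical copies can share. Without the naming style in the model the log2 fold changes were -2.25 for Nfil3 (-3.70 with it), -1.68 for Areg (-3.11) and -2.23 for Hist1h4a (-2.99). Ctla4 was 3.86-fold lower in bone (873 ± 150 against 2260 ± 330 CPM, adjusted p = 1.1e-05). Foxp3 did not pass (adjusted p = 0.87).

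Between bone and skin naive genes were higher in 9 of 16 cases, 11 and 1 lower adjusted over the list alone (adjusted p = 5.6e-07, and adjusted p = 0.17 with an estimated correlation). Tissue effector genes were lower in bone in 13 of 20 cases, 15 adjusted over the list alone (adjusted p = 2.5e-12, and adjusted p = 0.13 with an estimated correlation), cell cycle genes in 11 of 18, 17 alone (adjusted p = 2.3e-10, and adjusted p = 0.19 with an estimated correlation), NF-kB genes in 10 of 15, 12 alone (adjusted p = 1.1e-09, and adjusted p = 0.054 with an estimated correlation), and glycolysis genes in 4 of 16, 6 alone (adjusted p = 0.00033, and adjusted p = 0.18 with an estimated correlation). Examples were Ccr8 (4.11-fold), the cyclin gene Ccna2 (4.04-fold) and Cd83 (2.76-fold). A single B cell marker was higher, 5 adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.32 with an estimated correlation). Helper genes (adjusted p = 0.018) and markers of dendritic cells (0.022) and erythroid cells (0.0043) also passed as lower, with adjusted p = 0.19, 0.54 and 0.17 with an estimated correlation. Hbb-bt had 0 counts in both bone and skin, but 26 in Endo-style and 422 in Tregs-style spleen libraries. The erythroid call can therefore come from the style adjustment. Of the 10 highest and lowest genes 6 kept their call under every alternative, while Mreg (adjusted p up to 0.45), Hist1h4j (0.17), Areg (0.087) and Hist1h4a (0.085) did not. Mreg lost its call without any 1 bone or skin library or spleen replicate 1, 2 or 5 (adjusted p up to 0.21), and Hist1h4j without any 1 bone library or spleen replicate 1 or 2 (up to 0.068). The count was 777 without spleen replicate 2 and 842 without skin replicate 2. It was 2814 without the naming style in the model, which bone and skin do not share.

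Muscle and skin differed in 205 of 15617 genes, 97 higher and 108 lower in muscle. The interferon-induced GTPase genes Iigp1 (7-fold, log2 fold change 2.81 ± 0.44, adjusted p = 0.0034) and Tgtp2 (4.92-fold, adjusted p = 0.0011, uncertain because its copy Tgtp1 can take its reads) were higher in muscle. P2rx7 (6.55-fold), Bspry (6.07-fold) and the neuropeptide co-receptor gene Ramp1 (5.61-fold) were higher as well, and Itga4 was 4.82-fold higher (790 ± 120 against 120 ± 16 CPM, adjusted p = 2.4e-05). Lower in muscle were Rmrp (7.31-fold), the kinase gene Cdc42bpb (7.16-fold), Nfil3 (6.46-fold), Jag1 (6.22-fold) and Rpph1, the RNA of ribonuclease P (5.53-fold). Cxcr3, the receptor for interferon-induced chemokines, was 4.35-fold higher in muscle (99.5 ± 15 against 31.1 ± 4.4 CPM, adjusted p = 0.00012). The dioxin receptor gene Ahr was 2.75-fold lower (adjusted p = 0.00067), the chromatin organiser gene Satb1 2.88-fold lower and the integrin gene Itgb8, which activates transforming growth factor beta, 3.32-fold lower.

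As lists, tissue effector genes were lower in muscle than in skin in 6 of 20 cases, 12 with 2 higher adjusted over the list alone (adjusted p = 1.9e-07, and adjusted p = 0.23 with an estimated correlation). Cell cycle genes passed camera as lower (adjusted p = 4e-06, and adjusted p = 0.35 with an estimated correlation) with 0 of 18 members past edgeR's test and 2 adjusted over the list alone. Glycolysis genes passed likewise (adjusted p = 0.0014, and adjusted p = 0.2 with an estimated correlation), with 0 of 16 past edgeR's test and 4 adjusted over the list alone. Interferon genes were higher in 1 of 15 cases, 6 adjusted over the list alone (adjusted p = 5.8e-05, and adjusted p = 0.26 with an estimated correlation), and NF-kB genes lower in 1 of 15, 7 alone (adjusted p = 0.00029, and adjusted p = 0.2 with an estimated correlation). B cell markers were lower in 1 of 10 cases, 3 adjusted over the list alone (adjusted p = 0.00029, and adjusted p = 0.16 with an estimated correlation). Markers of erythroid cells (adjusted p = 0.00012, and adjusted p = 0.072 with an estimated correlation) and of dendritic cells and MHC class II (adjusted p = 0.0069, and adjusted p = 0.46 with an estimated correlation) also passed as lower. Hbb-bs and Hbb-bt had 0 counts in both muscle and skin, so the erythroid call can come from the style adjustment. With the replicate number as a block in place of the naming style, the calls on cell cycle genes (adjusted p = 0.23) and on markers of B cells (0.081), erythroid cells (0.78) and dendritic cells (0.37) were lost. Of the 10 highest and lowest genes only Iigp1 and Tgtp2 kept their call under every alternative, the other 8 reaching adjusted p of up to 0.39. P2rx7, Bspry, Ramp1 and Rmrp lost it without spleen replicate 2 (adjusted p of 0.085, 0.052, 0.14 and 0.092), without spleen replicate 1 or 5, and without several libraries of muscle and skin. Cdc42bpb and Jag1 lost it by limma-voom (0.072 and 0.12), Nfil3 without the naming style (0.11, log2 fold change -1.24 against -2.69 with it) and Rpph1 without the 2 spleen libraries richest in ribosomal RNA (0.13). Without the naming style in the model 749 genes changed. Without 1 library the count was 106 (spleen 2), 528 (spleen 3), 113 (spleen 5), 117 (muscle 3), 113 (skin 2) or 101 (skin 3).

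Heart and bone Tregs differed in 1064 of 15926 genes, 640 higher and 424 lower in heart. Ctla2a was 5.29-fold higher in heart (627 ± 210 against 112 ± 29 CPM, log2 fold change 2.40 ± 0.33, adjusted p = 0.00099), the Wnt pathway gene Dkk3 9.32-fold, the endothelin receptor gene Ednrb 7.6-fold, the prostaglandin D synthase gene Hpgds 5.4-fold and the apolipoprotein L gene Apol9b 5.26-fold. Il1rl1 was 2.33-fold (adjusted p = 0.00099), Ctla4 2.2-fold and Ccr8 3.15-fold higher. Lower in heart were the membrane gene Emp1 (4.66-fold), Nhsl2 (3.76-fold), the sodium pump gene Atp1b1 (3.51-fold), Zscan22 (3.44-fold) and Csf1 (3.36-fold, 10.6 ± 3.7 against 36.8 ± 2.6 CPM). Tissue effector genes were higher in heart in 9 of 20 cases, 13 adjusted over the list alone (adjusted p = 1.9e-07, and adjusted p = 0.19 with an estimated correlation). Helper genes were higher in 3 of 12, 4 alone (adjusted p = 0.00032, and adjusted p = 0.054 with an estimated correlation), and NF-kB genes in 3 of 15, 7 alone (adjusted p = 0.0016, and adjusted p = 0.33 with an estimated correlation). Lists of T cell identity (adjusted p = 0.02), chemokine receptors (0.049), cell cycle (0.025), interferon (0.049) and erythroid genes (0.0017) also passed as higher, with adjusted p = 0.34, 0.4, 0.64, 0.56 and 0.17 with an estimated correlation. Among cell cycle genes, however, heart replicates 1 and 2 lay below all bone libraries in Ccna2 (52.2 and 36.6 CPM against 56.6 to 71.3) and Plk1 (4.8 and 7.86 against 13.1 to 18.1), and only replicate 3 lay above (130 and 23.9). Markers of CD8 T and NK cells passed as lower (adjusted p = 0.017, and adjusted p = 0.3 with an estimated correlation). Of the 10 highest and lowest genes 9 kept their call under every alternative, and Hpgds lost it without heart replicate 2 (adjusted p = 0.059). Without 1 library the count was 456 (heart 2), 429 (bone b) or 460 (bone c).

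Heart and muscle differed in 72 of 15926 genes, 57 higher and 15 lower in heart. Bcl2 was 3.2-fold higher in heart (48.8 ± 12 against 15.8 ± 2.9 CPM, log2 fold change 1.68 ± 0.23, adjusted p = 0.00074) and Tcf7 2.73-fold higher. The annexin gene Anxa2 was 2.61-fold lower (61.1 ± 3.8 against 161 ± 23 CPM, -1.38 ± 0.19, adjusted p = 0.00074). The potassium channel gene Kcna4 was 9.89-fold, Ednrb 5.36-fold, Magi1 4.32-fold, the G protein regulator Rgs16 3.34-fold and Utp14b 3.34-fold higher, and Emp1 3.86-fold, Plcd1 3.2-fold, Lmna 2.91-fold and Csf1 2.73-fold lower. Naive genes were higher in heart in 5 of 16 cases, 10 adjusted over the list alone (adjusted p = 5.8e-14, and adjusted p = 0.054 with an estimated correlation). B cell markers were higher in 2 of 10 beside them, 5 alone (adjusted p = 2.5e-08, and adjusted p = 0.077 with an estimated correlation). Erythroid markers (adjusted p = 4e-06, and adjusted p = 0.054 with an estimated correlation) and helper genes (adjusted p = 0.014, and adjusted p = 0.17 with an estimated correlation) passed as higher, the latter not with the replicate block (0.1). Markers of CD8 T and NK cells (adjusted p = 0.0036, and adjusted p = 0.2 with an estimated correlation) and of endothelial cells (adjusted p = 0.012, and adjusted p = 0.17 with an estimated correlation) passed as lower. Of the 10 highest and lowest genes Anxa2 kept its call under every alternative, and the other 9 reached adjusted p of up to 0.33. The count was 30 without heart replicate 2, 29 without muscle replicate 2 and 27 without muscle replicate 3. Without heart replicate 2 adjusted p was 0.12 for Kcna4, 0.25 for Ednrb, 0.28 for Magi1, 0.061 for Utp14b, 0.1 for Emp1, 0.11 for Lmna and 0.12 for Csf1, and without muscle replicate 3 it was 0.097 for Rgs16 and Plcd1. Tcf7 lost its call with only the 2 groups in the model (0.056). Foxp3, Ctla4 and Areg did not pass (adjusted p of 0.96, 0.57 and 0.96).

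Heart and skin differed in 379 of 15926 genes, 237 higher and 142 lower in heart. Itga4 was 7.32-fold higher in heart (1020 ± 28 against 120 ± 16 CPM, log2 fold change 2.87 ± 0.20, adjusted p = 5.1e-09), Bcl2 8.61-fold, Bach2 7.57-fold and P2rx7 13.3-fold. Ccr9, a gut homing receptor gene, was 23.7-fold higher (73.8 ± 40 against 1.82 ± 0.71 CPM). Lower in heart were Cdc42bpb (8.47-fold), Maged1 (7.81-fold), Jag1 (6.69-fold), Mreg (6.16-fold) and Gcnt1, an enzyme of O-glycan branching (5.78-fold). Prdm1, the effector factor Blimp-1, was 2.86-fold lower (126 ± 9.4 against 309 ± 6.2 CPM, adjusted p = 8.1e-05). Tissue effector genes were lower in 6 of 20 cases and higher in 2, with 12 and 2 adjusted over the list alone (adjusted p = 4.3e-06, and adjusted p = 0.23 with an estimated correlation). Naive genes were higher in 6 of 16, 10 with 1 lower alone (adjusted p = 3.1e-10, and adjusted p = 0.06 with an estimated correlation), cell cycle genes lower in 1 of 18, 11 alone (adjusted p = 1.1e-09, and adjusted p = 0.22 with an estimated correlation), and glycolysis genes lower in 3 of 16, 8 alone (adjusted p = 2.5e-07, and adjusted p = 0.054 with an estimated correlation). NF-kB genes were lower in 4 of 15, 7 with 1 higher alone (adjusted p = 3.5e-05, and adjusted p = 0.2 with an estimated correlation), and B cell markers higher in 1 of 10, 4 alone (adjusted p = 0.025, and adjusted p = 0.46 with an estimated correlation). Interferon genes were higher in 1 of 15, 2 alone (adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation). Markers of dendritic cells and MHC class II (adjusted p = 0.02, and adjusted p = 0.53 with an estimated correlation) and of CD8 T and NK cells (adjusted p = 0.039, and adjusted p = 0.37 with an estimated correlation) passed as lower. Of the 10 highest and lowest genes 8 kept their call under every alternative. Ccr9 lost it without skin replicate 1 or 3 (adjusted p of 0.055 and 0.053), and Mreg without any 1 skin library, heart replicate 2 or 3 or spleen replicate 1 to 4 (up to 0.11). Without 1 library the count was 238 (heart 1), 216 (skin 1) or 205 (skin 3).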

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

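The tests of bone against muscle below (spleen-type cells, B cell RNA and dilution) were chosen only after the result was seen, and so was the omission of Dapl1 from the B cell RNA test.

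Tissues differed in their change against spleen by direct tests in 759 genes (bone and muscle), 1267 (bone and skin), 205 (muscle and skin), 1064 (heart and bone), 72 (heart and muscle) and 379 (heart and skin). Within these, 43 genes changed in opposite directions against spleen in 2 tissues, among them the chemokine receptor genes Cxcr3 and Ccr9. Bone and muscle were set against Tregs-style spleen libraries and skin against Endo-style ones, so a style difference in spleen can give opposite signs. For instance, Chka counted as opposite but lay below the spleen mean of 31 CPM in both bone (27.8 CPM) and skin (24.7 CPM).

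Some spleen libraries stood far from the other 5. Spleen replicate 1 had more Il1rl1 (82 against 45.5 to 51.7 CPM) and Itgae (84.2 against 46.9 to 56.1), both higher in injured tissues, and replicate 4 had less Tnfrsf9 (85.7 against 124 to 131) and Itgal (546 against 611 to 644). Replicate 5 had less Npnt (0.129 against 1.14 to 2.67) and more Jag1 (4.45 against 1.9 to 2.6). Replicate 6 had less Dgat2 (0.14 against 2.41 to 6.93), Lmna (4.64 against 9.52 to 14.5) and Csf3r (0 against 1.14 to 2.91), and a larger share of mitochondrial mRNA (4.88% against 2.31 to 3.25%). Of 159 measures tested in spleen 10 stood out in this way (6.29%), where chance gives about 1 in 20.

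Bone Tregs held naive genes above and tissue effector genes below muscle Tregs. B cell RNA in bone should leave naive genes that mature B cells do not use unchanged. The median log2 fold change of 4 such genes was 1.09 ± 0.44 (SE over genes). Among them Tcf7 was at 2.00 (adjusted p = 3.4e-07) and Lef1 at 0.61 (0.015), while Igfbp4 and Il7r did not pass (adjusted p = 0.055 and 0.067). Dapl1, at 0 counts in muscle, was left out, and with it the test was open. Precursors of B cells also use Il7r and Lef1, so B cell RNA as a cause stays open. Dilution by other cells should lower T cell identity genes as far as the tissue effector list, but the median log2 fold changes were -0.20 ± 0.05 over 12 genes and -0.70 ± 0.09 over 20, which argues against it as the whole cause. A share of spleen-type Tregs in the bone libraries stays open. With muscle as the profile of unmixed cells that share was 26.5 ± 3.9% from 439 genes lower in muscle and 43.6 ± 8.4% from 748 higher genes, 17.1 points apart (SD of the difference 4.5 over 3 libraries). Both lay above 0 in every bone library (22.5 to 51.5%), and the profile of unmixed bone Tregs is not known. A difference of the Tregs between tissues, which the design names, remains untested.

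Small RNA genes were lower in bone and muscle than in spleen. Against same-style spleen libraries alone, the median log2 fold change was -2.10 ± 0.13 in muscle and -2.05 ± 0.13 in bone. Small RNA genes were thus lower also within the Tregs naming style. The adjusted folds already rest on those spleen libraries, so this repeats the main comparison and is no separate test of style. Within spleen the mean log2 CPM of small RNA genes was 1.43 in the Endo and 2.24 in the Tregs style. Carry-over of ribosomal RNA was tested over the 6 spleen libraries, where the level of small RNA genes correlated with the ribosomal share at r = -0.37 (exact permutation p = 0.48, and r = 0.88 without the 2 libraries farthest out). That test leaves carry-over open, as are RNA quality and differences between tissues.

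The count of genes changed between muscle and skin moved with the model. Across 15926 genes the difference between spleen naming styles correlated with skin minus muscle at r = 0.29, which is consistent with a batch in that comparison. The same correlation was 0.2 for skin and bone, and 0.04 for bone and muscle, which share a style. In heart, where a single library has the Endo style, the difference between styles correlated with that of spleen at r = 0.08, under the bar of 0.1 set for skin and muscle. Of the 205 genes called after adjustment 97.6% kept their direction without it, while 63.4% (SE 3.4) also differed the same way between the styles of heart, above the bar of 60% that would go against a tissue difference. As that value lies within 2 SE of the bar and rests on a single Endo heart library, a tissue difference beyond naming style stays open.

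Other splits of the libraries into groups of the same sizes were counted as well. For heart against spleen only the real split of 84 gave 3043 genes (1 of 84, highest other 41). That is the smallest share that 84 splits can give, which argues against chance but cannot exclude it. Mixed splits also carry tissue differences into the spread within groups, which lowers their counts. For bone, muscle and skin against spleen, fitted with only the 2 groups and the naming style, 2 of the 84 splits gave as many genes as the real one (2121, 3449 and 4701). The other of the 2 was the 3 spleen libraries of that tissue's naming style against the rest, which in this model is the same contrast. The next highest of those fitted with the style gave 27, 19 and 9. As the folds rest on those 3 spleen libraries and many splits move libraries across styles, the share of 2 in 84 cannot exclude chance. The 3 spleen libraries of the other style against the rest could not be fitted with the style, and gave 250, 40 and 64 without it. Between tissues 10 splits are too few for a share under 0.05. Real values and highest others were 614 and 0 (bone and muscle), 4272 and 4 (bone and skin), 1442 and 3 (muscle and skin), 1157 and 1 (heart and bone), 23 and 0 (heart and muscle), and 598 and 0 (heart and skin), with 1 split as large in each case.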

How the results depend on the processing

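The alternatives that leave out 2 ribosomal RNA-rich spleen libraries or bone replicate c, or keep protein-coding genes only, were chosen after the results were seen. Requiring at least 2-fold left 1334 genes in bone, 2289 in muscle, 2551 in skin and 1672 in heart against spleen, 743 shared by bone, muscle and skin, 587 shared by all 4, 311 between bone and muscle, 840 between bone and skin and 424 between heart and bone. Splitting the spleen libraries between tissues left 894 shared by bone, muscle and skin. Without the naming style 432 genes changed between bone and muscle, 2814 between bone and skin, 749 between muscle and skin and 742 between heart and skin. Without a filter the counts were 1191 (bone and muscle), 618 (muscle and skin), 380 (heart and muscle) and 909 (heart and skin). DESeq2 gave 1270 (bone and muscle), 427 (muscle and skin), 1630 (heart and bone), 211 (heart and muscle) and 672 (heart and skin), and limma-voom 843 (bone and skin), 75 (muscle and skin) and 250 (heart and skin). With only the 2 groups in the fit the counts were 4272 (bone and skin), 1442 (muscle and skin), 23 (heart and muscle) and 598 (heart and skin). Without the ribosomal RNA-rich spleen libraries they were 2548 (skin against spleen), 705 (bone and skin), 126 (muscle and skin) and 638 (heart and skin), and without bone replicate c 256 (bone and muscle) and 460 (heart and bone). Apart from the test of naming style between muscle and skin above, the cause was not tested. The stricter 2-fold threshold can only leave fewer calls. In the simulated data 17.9% of DESeq2 calls and 7.89% of edgeR calls were false for bone against muscle. These shares were 18.4% and 8.57% for muscle against skin, and 17.3% and 7.48% for heart against muscle. The other alternatives kept the counts within 1.5 times, apart from the replicate block and single libraries left out, given next.

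Leaving out 1 library at a time gave 1784 to 2604 genes in bone, 3257 to 4257 in muscle, 3368 to 4495 in skin and 2241 to 2894 in heart against spleen, 1087 to 1462 shared by bone, muscle and skin and 893 to 1143 shared by all 4. Between tissues it gave 256 to 1040 (bone and muscle), 777 to 1705 (bone and skin), 101 to 528 (muscle and skin), 429 to 1115 (heart and bone), 27 to 104 (heart and muscle) and 205 to 522 (heart and skin).

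With the replicate number as a block in place of the naming style, 1090 genes changed between muscle and skin and 806 between heart and skin, and 4707, 4278 and 2582 in muscle, skin and heart against spleen. Libraries of 1 number correlated at -0.13 to 0.1 after removal of group means (18 pairs), and 2 of 12 libraries correlated best with their own number. Bone was left out of these fits, because the labels of its replicates 2 and 3 give no library name that would tie them to columns. Of the list tests without bone, 67 passed and 64 with the block, 58 of them in both. Calls lost with the block, with their adjusted p, were coinhibitory receptors (0.059) in skin and markers of B cells (0.095), erythroid cells (0.46) and fibroblasts (0.11) in heart against spleen, helper genes between heart and muscle (0.1), and cell cycle (0.23) and markers of B cells (0.081), dendritic cells (0.37) and erythroid cells (0.78, with the direction turned) between muscle and skin. Calls gained were immediate early genes in muscle against spleen (0.0065), markers of endothelial cells as higher in muscle than in skin (0.047), chemokine receptors (0.046) and markers of neutrophils (0.045) as higher and cell cycle genes (0.00095) as lower in heart than in muscle, and erythroid markers as higher in heart than in skin (0.036, lower without the block).

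With an estimated correlation 0 camera tests passed (lowest adjusted p 0.054), against 105 with the preset. Upper-quartile scaling shifted the balance of higher and lower genes to 1982 and 2044 in muscle, 2026 and 2468 in skin and 1506 and 1643 in heart against spleen, and to 463 and 285 between bone and muscle, 672 and 560 between bone and skin and 564 and 539 between heart and bone. Of the named genes 2 turned direction. Vcam1 in skin against spleen had a log2 fold change of 0.07 without the 2 ribosomal RNA-rich spleen libraries (adjusted p = 0.97), and Dcn in muscle against spleen values from 0 without muscle replicate 1 (adjusted p = 1) to 8.87 without muscle replicate 2. Depth limits genes near the filter, and the spleen libraries of the Endo style were the shallowest.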

Other observations

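Genes that changed in opposite directions in 2 tissues included receptors of T cell migration and signalling, and were picked here after their values were seen. Cxcr3 rose in muscle (log2 fold change 0.85, 99.5 CPM) and fell in skin (-1.27, 31.1 CPM) against 64.2 CPM in spleen, with an adjusted p of 0.00012 for the difference. Ccr9 fell in skin (-3.12, 1.82 CPM) and rose in heart (1.58, 73.8 CPM) against 20.6 CPM in spleen (adjusted p = 0.0082 for the difference). Ctsw, a cysteine protease gene of cytotoxic lymphocytes, fell in skin (-1.54) and rose in heart (1.20), with adjusted p = 0.0011 for the difference. Socs1, a suppressor of cytokine signalling, rose in bone (0.67, 46.3 CPM) and fell in muscle (-0.60, 19.1 CPM) against 32.8 CPM (adjusted p = 0.0017 for the difference). Myb, a transcription factor gene, fell in bone (-0.71, 26.9 CPM) and rose in skin (1.33, 52.2 CPM) against 31.9 CPM (adjusted p = 0.00028 for the difference). Myb was itself lower in Endo-style than in Tregs-style spleen libraries (log2 fold change -1.1, edgeR adjusted p = 0.0082). Its opposite calls therefore lean on which spleen libraries each tissue was set against.

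Between spleen libraries of the 2 naming styles 741 genes differed in the fit of bone, muscle and skin, 259 higher and 482 lower in the Endo style. Among the lower ones, picked after their values were seen, were the transcription factor genes Bhlhe40 (log2 fold change -1.60), Nfil3 (-1.45) and Nr4a3 (-1.30), while Anxa1 was higher (2.39). Several small RNA genes differed by more, lower for Snord100 (-7.18) and Snord87 (-5.24) and higher for Mir6240 (5.56). Lists of cell cycle (adjusted p = 0.00017), immediate early (0.00034) and erythroid genes (1.7e-05) were lower in the Endo style, with adjusted p = 0.61, 0.61 and 0.074 with an estimated correlation. In the heart fit 48 genes differed by style, and 131 in the joint fit of all libraries.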
